A study of Drosophila melanogaster with 18 samples.

How the data were processed

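Per the labels, each sample was 1 of 3 sets of replicate spots on a 2-colour slide that carried total RNA of Drosophila melanogaster switched to banana in one channel and of a cornmeal control in the other. The slides were paired as dye flips, and the slide, the spot set and the flip partner were taken from the labels of each sample. The deposited table held 18 columns of log ratios over 5620 probes, and all of its columns were used. How the authors scanned, background-corrected, filtered or normalised the slides is not given in the sources used here. Dyes, the direction of the ratio and the base of the logarithm are likewise not given. The deposited values were taken as log2 ratios, because their range of -16.02 to 13.21 exceeds 11.09, the natural logarithm of the highest 16-bit signal. The lowest value also lies just beyond 16, the log2 of that signal, so the bound does not settle the base, which remains an inference. Channel intensities and backgrounds were not used here, so no within-slide loess, background correction or filter on dim spots could be applied, and how far spots lay above background is unknown. Large ratios can come from spots near background in one channel.

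The columns were not centred on a common value. Column medians lay between -0.69 and 0.35, medians of the spot sets of a slide differed by 0.278 to 0.961, and slide medians lay between -0.20 and 0.16 before centring. No pair of columns shared more than 0.021% identical values. Between 4860 and 5149 probes had a value in a column, 3911 probes had a value in all 18 columns and 24 had none.

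Genes were named from the platform annotation given for the table. A single gene was listed for 4955 probes, several genes for 85 and none for 580. The gene identifiers of 4876 of the 4955 probes were found in the reference gene table of the Release 6 assembly, in which 0 symbols differed, and 79 probes kept the symbol of the annotation. Because no genome build is named for the probes in the sources used here, no coordinates are given. Probes with several genes or none were tested alone and not named.

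The 3 spot sets of a slide were averaged, each slide was centred on its median, and probes of 1 gene were averaged, which applied to 329 tested genes with more than 1 probe. The sign of slides with cornmeal RNA in channel 1 was then turned, and the slides of each flip pair were averaged. This cancels an additive channel effect for probes with values on both slides, but 86 genes took in, in some pair, a probe with a value on 1 of its slides, for which it does not cancel. Spot sets are repeat spots, and a dye flip is a repeat hybridisation, so neither was counted as a replicate. The 3 pair ratios of the 4723 rows with values on both slides of all 3 pairs, comprising 4144 named genes and 579 unnamed probes, were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 2.12 prior degrees of freedom. The channel effect was tested in the same way on slide values that had not been turned. Differences between pairs were tested with a limma F test on the 6 turned slides with terms for pair and orientation. In that test the slides of a pair are technical repeats, so it shows that hybridised RNA pairs differed beyond hybridisation noise, and it does not measure biological spread. The pairing of slides comes from the labels, which name the flip partner of each slide.

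Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes per sign with the largest ratio past the adjusted threshold with one sign in all 3 pairs, and filled missing places by unadjusted p among genes with one sign in all 3 pairs. Because 0 genes passed, all 20 named genes were chosen by unadjusted p and do not pass. The 2 members with the smallest p of each list were also named. Lists with at least 4 measured genes were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

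The procedure was tested on simulated spots with the spreads and missing values of the real rows. Of 100 genes given a log2 change of 1, 52% passed the adjusted threshold for the diet comparison and 92% the unadjusted one, with a median estimate of 0.979. Of 100 genes given a change of 2, 86% passed the adjusted threshold. In the same fit 6 unchanged rows of the 4723 passed. A shift of 0.5 in an 18-gene list was detected by camera, and 0 of the 20 unshifted lists passed. For differences between pairs, 92% of 100 genes made to differ by 8 between pairs 1 and 3 passed, with 3 unchanged rows. A test for small F-test p-values within a list, whatever the direction of the difference, found the list made to differ and 0 other lists. Rows were drawn independently of each other. The list results therefore do not show how the preset correlation performs where members of a list vary together. Separate noise between the slides of a pair was added only in the draws for pair differences. In those draws the slide noise also held the channel effect, which was added again, and other rows had no spread between pairs. In the diet draw many genes changed in 1 fit, which loosens the adjusted threshold. The shares detected are therefore not those of the real data.

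Alternatives covered the centring and scaling of slides, the summary of spot sets, incomplete rows, single probes, the unit of replication, variance shrinkage, values taken as already turned by the authors and each pair left out in turn. Scaling brought the centred slides to one median absolute value with normalizeMedianAbsValues of limma. Centring each spot set by itself, gene means over probes with both slides of a pair, list tests of the differences between pairs, and list shifts after scaling or quantile normalisation were added after the data had been seen.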

Results

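Total RNA of Drosophila melanogaster switched to a banana diet was hybridised against RNA of animals kept on cornmeal, the control diet, on 2-colour spotted arrays. The series comprised 6 slides, and each slide carried 3 sets of replicate spots, so that the table held 18 columns of ratios, taken as log2, over 5620 probes. In 9 columns from 3 slides the banana RNA was in channel 1, and in the other 9 columns from 3 slides the cornmeal RNA was in channel 1. The slides formed 3 dye-flip pairs, each made of 1 slide per orientation, and the flip pair was the unit of replication (n = 3). The labels do not say that the pairs came from separate cultures, so the p-values measure the spread between these pairs, which may be technical. They name no stage, sex or tissue. Between 4860 and 5149 probes had a value in a column. The number of arrays limits the precision of every ratio.

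The labels do not state whether the ratios run channel 1 over channel 2 or the reverse. All slides were therefore turned to the sign of the slides with banana RNA in channel 1, and ratios are called positive or negative in that sense. A positive ratio means a higher level on banana if the deposited values are channel 1 over channel 2, and a higher level on cornmeal if they are channel 2 over channel 1. The same limit applies to every signed value, and no diet is named as the higher one.

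The first comparison addressed which genes differed in transcript level between animals moved to banana and animals on cornmeal. No gene passed the multiple-testing threshold, and the genes with the smallest p-values and one sign in all 3 pairs had ratios of 1.57-fold to 3.37-fold. CG10962 had the smallest p-value, with a log2 ratio of 1.75 ± 0.115 (SD, n = 3), a 3.37-fold difference, and it was positive on 6 of 6 slides (limma adjusted p = 0.275). Among genes of known function with positive ratios, the gut lipase gene mag stood at 1.14 ± 0.221, the cytochrome P450 gene Cyp9b2 at 1.21 ± 0.269 and the peroxisomal acyl-CoA oxidase gene Acox57D-p at 0.74 ± 0.106 (SD, n = 3 each). On the negative side, the cold-inducible gene Fst stood at -1.10 ± 0.193, the kinesin-associated protein gene Kap3 at -1.23 ± 0.311 and CG10912 at -1.23 ± 0.307 (SD, n = 3 each). These 6 genes had the sign of their mean on 6 of 6 slides, and the limma adjusted p was 0.411 for each of them.

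With limma, 0 of the 4723 rows tested passed an adjusted p of 0.05, and 380 rows had an unadjusted p under 0.05, where 236 were expected by chance. Of these 380 rows, 208 were positive and 172 were negative. One sign in all 3 pairs was found for 1441 rows, or 30.5%, against 25% for independent signs, and one sign on all 6 slides for 314 rows, or 6.65%, against 3.125%. The plain one-sample statistic without shared variance gave 0 genes past the adjusted threshold and 324 past the unadjusted one. The unadjusted count was 577 without pair 1 and 210 without pair 2, with 0 genes past the adjusted threshold in limma in either case. The 6 slides fitted with the flip pair as a random replicate block gave 1 gene, CG10962 (limma adjusted p = 0.0156), and with no block also 1 gene. The estimated correlation between the slides of a pair was -0.102 in the blocked fit, and both fits count the slides of a pair as separate replicates. Had the authors already turned the deposited values, 9 of the 20 named genes, CG10962 and Cyp9b2 included, would take the opposite sign, and others would lie near 0, such as Acox57D-p at 0.01 and Kap3 at -0.01.

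Of the other genes named for a positive ratio, nod, a kinesin-like gene of female meiosis, reached 1.15 ± 0.328, CG3270 0.82 ± 0.163 and the planar cell polarity gene sano 0.74 ± 0.093 (SD, n = 3 each), all positive on 6 of 6 slides. The mean of 1.29 ± 0.114 for dlg1, a scaffold gene of septate junctions, combined 3 probes that disagreed, and its small SD comes from their mixture. One probe averaged 1.79, with 0.64, 1.97 and 2.76 in the 3 pairs, another averaged 0.103, and the last had no pair ratio but entered the mean of single slides. Over probes with both slides of a pair dlg1 averaged 0.95, and over the 18 spot sets 0.48 (limma adjusted p of 0.451 and 0.456). The nucleoside transporter gene Ent1 had a pair-based ratio of 1.15 ± 0.249 (SD, n = 3), but its turned slide values were 4.04 and -1.21 in pair 1 and 2.37 and -0.10 in pair 2, so that 2 of 6 slides had the opposite sign. With slides as units its limma adjusted p was 0.705 with and 0.632 without a replicate block for the pair. CG42322 (0.89 ± 0.218, SD, n = 3) was negative on 1 slide of pair 3, at -0.15. Its limma adjusted p with slides as units was 0.47 with and 0.379 without a replicate block.

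Among the other genes named for a negative ratio, the predicted aminopeptidase genes CG31233 and CG8773 had values of -0.65 ± 0.066 and -0.67 ± 0.097. CG32302 had -0.76 ± 0.16, the predicted chitin-binding protein gene CG6933 -0.77 ± 0.187 and CG9021 -1.05 ± 0.3 (SD, n = 3 each), all negative on 6 of 6 slides. CG11696 (-1.06 ± 0.212) was positive on 1 slide of pair 1, at 0.69, and the kinase gene Pdk1 (-0.74 ± 0.041) was positive on 1 slide of pair 3, at 0.15. The small SD of Pdk1 is one of pair means whose slides disagreed, with -1.70 and 0.15 in pair 3. With slides as units the limma adjusted p was 0.597 for CG11696 and 0.543 for Pdk1 with a replicate block for the pair, and 0.483 and 0.438 without. On the pair ratios the limma adjusted p was 0.411 for all genes of both signs named by rule apart from CG10962.

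**Figure D1:**
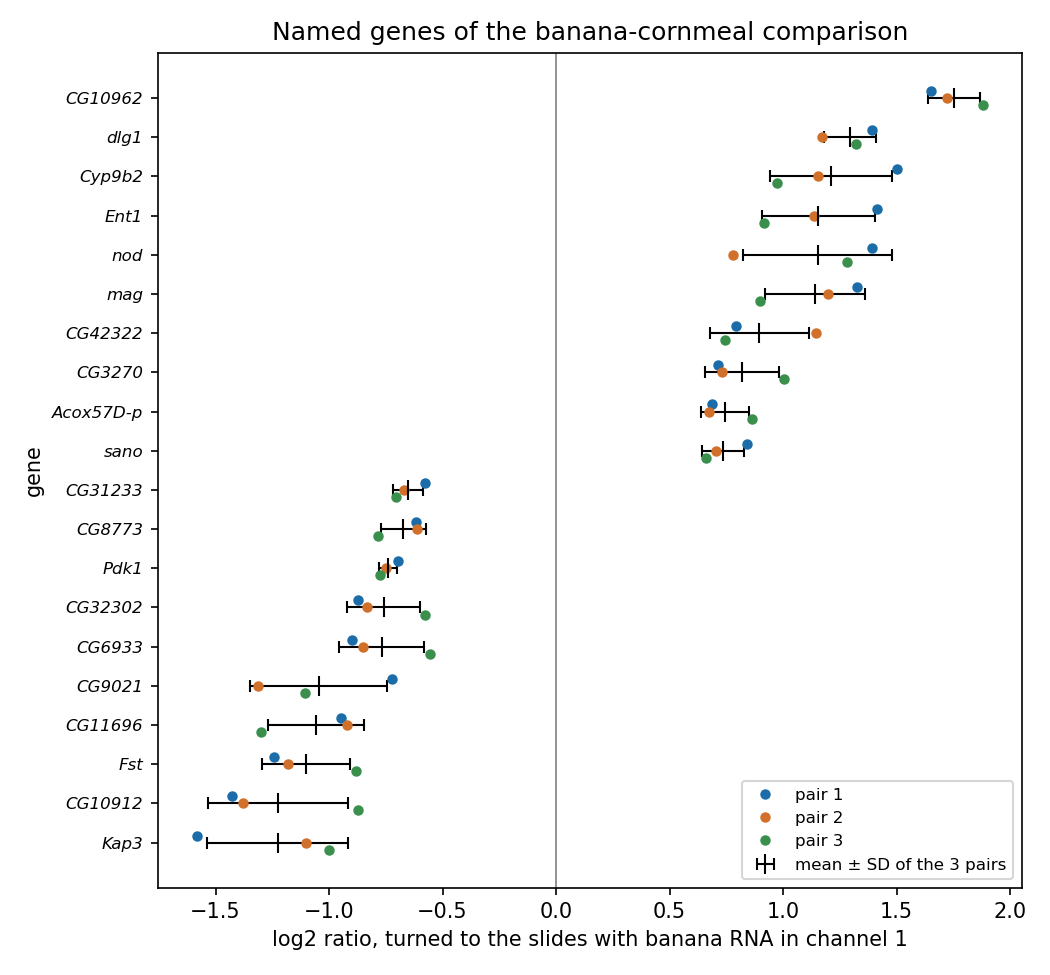
Turned log2 ratios of the 20 named genes (x axis) in each of the 3 flip pairs (coloured points), with the mean and SD of the pairs (n = 3). CG10962 lay farthest to the positive side at 1.75, and Kap3 and CG10912 lay farthest to the negative side at -1.23, and none of the 20 passed the adjusted threshold.

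A ratio over 1 in size on the log2 scale in each of the 3 pairs, with one sign, was found for 5 genes or unnamed elements, which were singled out after their values were seen. Of these, dlg1 met it only as a mean of probes, none of which met it alone. The others were CG10962 and 3 with a wider spread. A single array element without a gene name in the annotation had the largest mean, 5.47 ± 2.44 (SD, n = 3), with pair values of 7.30, 2.71 and 6.41. The lysosomal alpha-mannosidase gene LManV had 2.36 ± 1.12, and the aspartic protease gene Bace had -2.36 ± 1.38 (SD, n = 3 each). The limma adjusted p values of these 3 were 0.411, 0.411 and 0.461.

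Gene lists fixed in advance showed whether functional groups shifted together. Of 27 lists, 21 had the minimum of 4 measured genes. The muscle, cytochrome P450 and heat shock lists shifted to positive ratios relative to the other genes (camera with a preset correlation of 0.01, adjusted p of 0.00159, 0.00482 and 0.0394). None of the 3 passed with an estimated correlation, where the adjusted p was 0.87 for each. With fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, 0 lists passed and the smallest adjusted p was 0.518. For change in either direction fry gave adjusted p of 0.0706 for cytochrome P450, 0.28 for muscle and 0.529 for heat shock genes. Had the authors already turned the deposited values, the list medians would be 0.07 for muscle, -0.066 for cytochrome P450 and -0.046 for heat shock genes. None of the 3 would then pass (camera with the preset correlation, adjusted p of 0.478, 0.478 and 0.968).

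All 9 measured muscle genes had a positive mean ratio, with a list median of 0.38, and 5 of them were positive in all 3 pairs. The largest values among the members with an unadjusted p under 0.05 were those of the thick-filament gene Mf, 0.65 ± 0.355, the projectin gene bt, 0.55 ± 0.211, and the troponin T gene up, 0.45 ± 0.145 (SD, n = 3 each). Adjusted over the list alone, 0 of the 9 muscle genes passed, with a smallest limma adjusted p of 0.0544.

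Of the 29 cytochrome P450 genes, which encode monooxygenases of hormone, fatty acid and xenobiotic metabolism, 13 were positive in all 3 pairs, 2 were negative in all 3 and 14 were mixed. The list median was 0.17, and without pair 1 or without pair 2 it was 0.14 and 0.15, with adjusted p of 0.0873 and 0.0848. By p-value Cyp9b2 led the list, followed by Cyp6g1, a gene known from insecticide resistance, at 0.67 ± 0.211 (SD, n = 3). Cyp9b2 was the 1 member that passed adjusted over the list alone (limma adjusted p = 0.0269), and 0 passed over all genes tested.

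All 8 heat shock genes had a positive mean ratio, with a median of 0.29, and 3 were positive in all 3 pairs. The small heat shock genes spread widely between pairs. Hsp22 averaged 0.89 ± 0.776 (SD, n = 3), and Hsp26 averaged 1.04 ± 1.62 with 2.91 in pair 1, -0.03 in pair 2 and 0.25 in pair 3. The co-chaperone gene DnaJ-1 averaged 0.36 ± 0.463 (SD, n = 3). Without pair 1 the median of the list was 0.10 with an adjusted p of 0.206, and without pair 3 it was 0.28 with an adjusted p of 0.051.

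**Figure D2:**
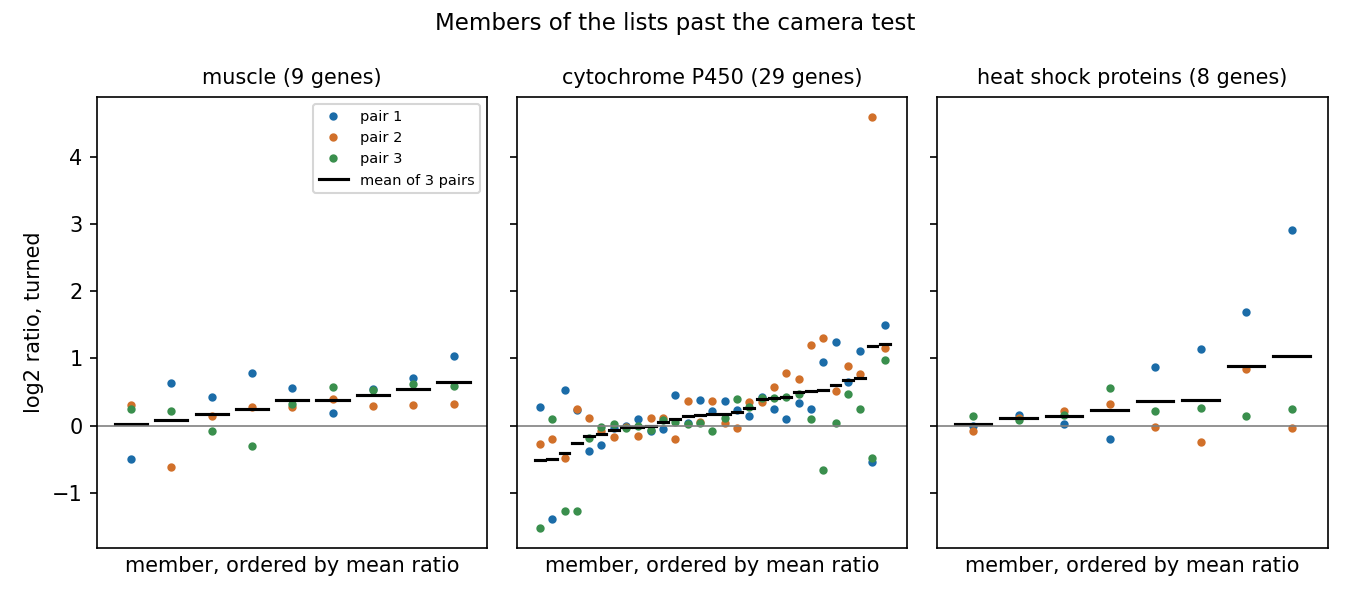
Turned log2 ratios (y axis) of the measured muscle (9), cytochrome P450 (29) and heat shock (8) genes, ordered by mean, with a point per flip pair and a bar at the mean of the 3 pairs. All means of the muscle and heat shock genes lay above 0, and 19 of the 29 cytochrome P450 means did, but the points of single genes scattered across 0.

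Digestive and nutrient genes gave a few values that passed only within their own list. All 3 measured digestive serine proteases, too few for a list test, were negative in all 3 pairs, with yip7 at -0.88 ± 0.28 and Jon65Aiii at -0.81 ± 0.406 (SD, n = 3 each). Both passed adjusted over the list alone, where the smallest limma adjusted p was 0.0101, and neither passed over all genes. The starch-digesting amylase gene Amy-p had 1.04 ± 0.974 (SD, n = 3) with pair values of 1.12, 0.02 and 1.97, and the maltase gene Mal-A5 had 0.07 ± 0.254. Of 10 lipid genes, mag alone passed adjusted over the list alone (limma adjusted p = 0.00771), and the desaturase gene Desat1 had -0.45 ± 0.261. Of 4 alcohol and aldehyde genes, Aldh-III (0.58 ± 0.193) passed within its list at an adjusted p of 0.0328, and T3dh had 0.22 ± 0.334. In the list of 7 trehalose and gluconeogenesis genes, the trehalose-phosphate synthase gene Tps1 had -0.59 ± 0.196 and the glycogen phosphorylase gene Glyp -0.55 ± 0.281, and 0 passed within the list (smallest limma adjusted p = 0.055). In the nutrient-signalling list of 9 genes, the adipokinetic hormone receptor gene AkhR had 0.57 ± 0.143 and sug -0.53 ± 0.456, and 0 passed within the list (smallest limma adjusted p = 0.0536).

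The remaining metabolic and housekeeping lists with at least 4 measured genes did not pass the camera threshold. Their median ratios were 0.03 for 8 glutathione S-transferases, 0.07 for 6 UDP-glycosyltransferases, -0.02 for 6 glycolytic genes and 0.07 for 8 tricarboxylic acid cycle genes. They were 0.08 for 14 oxidative phosphorylation genes, 0.06 for 18 mitochondrial ribosomal proteins, 0.00 for 14 proteasome genes and 0.10 for 3 cytosolic ribosomal proteins, too few for a list test. Their leading members by p-value were GstO2 (-0.45) and GstS1 (0.15), Ugt316A1 (0.39) and Ugt36E1 (-0.13), Hex-A (-0.16) and Pfk (0.10), and Idh (0.30) and ScsbetaG (0.21). In the organelle and ribosome lists they were ATPsynC (0.23) and ND-51 (-0.14), mRpL10 (0.27) and mRpS29 (-0.19), Rpn5 (-0.20) and Rpt2 (-0.12), and RpS15Ab (0.13) and RpS28b (0.10).

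Stage and tissue markers other than muscle did not pass the camera threshold between the diets where at least 4 genes were measured. The median was 0.22 for 13 cuticle protein genes, 0.10 for 7 glue and ecdysone-response genes and 0.08 for the 16-gene gut and peritrophic matrix list. It was 0.05 for 5 neural genes and 0.03 for 6 haemocyte genes. Besides Muc68D and Peritrophin-A, the gut and peritrophic matrix list held Vha genes, chitinase (Cht) genes and obst genes, caught by their symbols. That list therefore does not stand for gut alone. The 4 measured peptidoglycan recognition proteins of the immune list had a median of 0.23, led by PGRP-LB (0.35) and PGRP-LD (0.59). The cuticle gene Cpr72Ea had a ratio of 0.65 ± 0.058 (SD, n = 3) and passed adjusted over the list alone (limma adjusted p = 0.0282), while Cpr72Ec had -0.23. In the gut list VhaM9.7-c had 0.39 and Peritrophin-A 1.12, in the ecdysone list ImpL2 had 0.18 and ftz-f1 0.88, in the neural list nSyb had -0.32 and elav -0.19, and in the haemocyte list NimC1 had 0.19 and Pxn -0.07. In the 4-gene yolk and chorion list (median 0.04) the yolk protein gene Yp2 had 0.06. The other members were Cp110 (0.29) and Cp190, centrosomal protein genes caught by their symbols, and fln, a flight muscle gene. The 3 male genes, too few for a list test, had a median of -0.10, with ocn at -0.27 and Acp36DE at 0.16. The larval serum and odorant lists had 0 measured genes and were not tested.

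The second comparison separated the part of each ratio that did not turn with the dye flip. With limma, 0 rows passed the adjusted threshold for this channel effect, 434 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0599. CG11436 led with a channel component of 1.88 and CG32533 followed with 3.35 (adjusted p = 0.0748). Without pair 2, 12 genes passed the adjusted threshold. Mitochondrial ribosomal proteins shifted towards negative channel values as a list, with a median of -0.21 (camera with the preset correlation, adjusted p = 0.0105), and 1 list in all passed. For the channel effect the lists were not tested with an estimated correlation or with fry.

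The third comparison asked whether the banana-cornmeal ratio differed between the 3 flip pairs by more than between the slides of a pair. It did for 5 genes, named after their values were seen, and in each of them pairs 1 and 2 were positive and pair 3 was negative. CG9083 had ratios of 7.55, 1.84 and -5.48 in pairs 1, 2 and 3 (limma F test, adjusted p = 0.0153). TwdlF, a cuticle protein gene of the Tweedle family, had 5.78, 2.44 and -4.89 (adjusted p = 0.0381), and Osi14, of the Osiris family, had 5.25, 2.13 and -2.41 (adjusted p = 0.0381). CG7080 had 2.54, 2.45 and -2.75 (adjusted p = 0.0381), and the gene with Entrez identifier 46066 had 2.41, 1.84 and -2.58 (adjusted p = 0.0395). In these 5 genes both slides of a pair had the same sign in every pair, and the smallest slide value of pairs 1 and 3 was 1.77 in size. In the same fit 432 rows had an unadjusted p under 0.05.

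The number of such genes rose when rows with incomplete spots were left out. Among the 3742 rows with all 18 values, 108 passed the adjusted threshold, of which 98 were named genes and 106 had an unadjusted p under 0.05 in the fit to all rows. The 3 of the 5 genes that had all 18 values, TwdlF, Osi14 and the gene with Entrez identifier 46066, were among them. CG9083, with the largest difference, and CG7080 lacked a value in some columns and were not in that fit. The median over spot sets in place of the mean gave 26 genes, and slides without centring gave 12.

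Cuticle protein and ecdysone-response genes had smaller p-values for pair differences than other genes, as did 3 other lists. This came from a one-sided camera test on the p of the F test, with the preset correlation (adjusted p of 1.2e-06 and 0.0116). It ranks differences against the noise between slides, in either direction, and not by their size. With this test no estimated correlation can be had, and it was chosen after the differences were seen. Of 12 cuticle protein genes with complete values 6 were among the 108, with the further Tweedle genes TwdlL at -1.31, 5.52 and 1.41 and TwdlW at 0.19, 2.29 and -0.90 in pairs 1, 2 and 3. Of 6 ecdysone-response genes 2 were included, the nuclear receptor gene ftz-f1 at 1.00, 2.33 and -0.71 and ImpL1 at 2.44, -0.59 and -1.93. The gut and peritrophic matrix list did not pass the same test over all genes (adjusted p = 0.132) and passed over those with all 18 values (adjusted p = 0.0308), where 4 of its 14 genes were among the 108. They were the chitin-binding protein genes obst-A (2.08, 3.53 and -0.41) and Peritrophin-A (1.08, 2.01 and 0.23) and the chitinase genes Cht7 (1.54, 1.56 and -0.46) and Cht5 (1.75, -1.31 and -0.51).

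**Figure D3:**
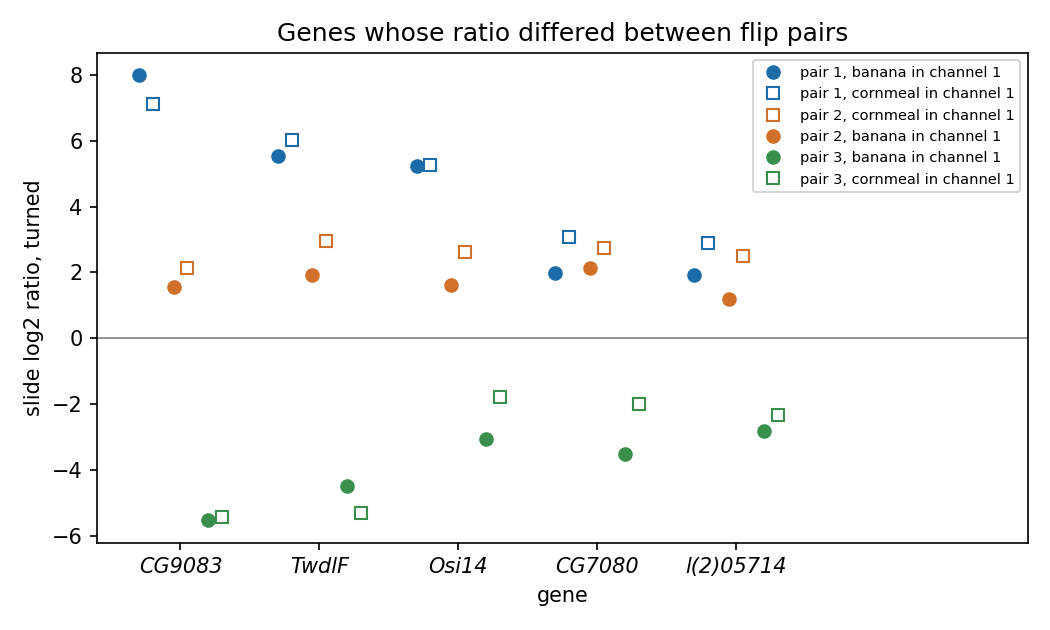
Turned log2 ratios (y axis) of the 5 genes whose ratio differed between flip pairs, with a point per slide, coloured by pair and shaped by the RNA in channel 1; the gene farthest right has Entrez identifier 46066. Both slides of pair 3 lay below 0 for each gene, and both slides of pairs 1 and 2 lay above 0.

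The fourth question was which level of the design limited the precision. The median SD over probes was 0.206 between spot sets of a slide after each set was centred, 0.347 between the turned slides of a pair and 0.221 between pair means. The SD between turned slides also holds the channel effect of a probe, which cancels in the pair mean. The SD between pairs is one of means of 2 slides. The 3 SDs are therefore not of one kind and do not settle which level limited the precision. Across genes, which are not independent replicates, the Spearman correlation between spot sets of a slide ranged from 0.503 to 0.736. The Pearson correlation, the measure planned, ranged from 0.316 to 0.6. The deposited ratios of the slides of a pair correlated at -0.179 in pair 1, -0.23 in pair 2 and 0.116 in pair 3 (Spearman), where a diet response alone gives a negative value before turning. The Pearson correlations were -0.205, -0.382 and -0.087, so that the sign in pair 3 depended on the measure. Turned pair ratios correlated across genes at 0.069 between pairs 1 and 2, -0.082 between pairs 1 and 3 and 0.351 between pairs 2 and 3 (Spearman). Pearson correlations of the same ratios were 0.161, -0.173 and 0.17, so that pairs 1 and 2 then correlated about as much as pairs 2 and 3.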

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

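The tests of a faulty slide, exchanged labels, the moulting cycle, slide structure, a technical batch and list differences between pairs were chosen after the results were seen, as was the reading of planned list tests as a single pair or shared noise.

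The banana-cornmeal ratio differed between flip pairs 1 and 3 for 5 genes past the adjusted threshold of the limma F test. The difference of pair 1 minus pair 3 was 13.03 on the log2 scale for CG9083, 10.67 for the cuticle gene TwdlF and 7.66 for Osi14. It was 5.29 for CG7080 and 4.99 for the gene with Entrez identifier 46066. Of the 15 ways to pair the 6 slides, 1 gave 5 genes, the real pairing, and the highest other count was 4. At an unadjusted p under 0.05 the real pairing gave 432 genes and the highest other pairing 692. That other pairing joined slides 29 and 25 and slides 30 and 28, which share an orientation, so it is not like a dye flip. Among pairings that joined only slides of opposite orientation, the highest other count was 278. The 15 pairings are too few for a share under 0.05.

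A single faulty slide cannot be judged from these 5 genes. Both slides of pairs 1 and 3 carried the sign of their pair, with a smallest size of 1.77, but the F test that picked them favours genes whose slides agree. A separate pick took 78 genes with a difference over 3 on the slides with banana RNA in channel 1. Of these, 70.5% kept the sign of that difference on the other slides (exact 95% interval 59.11 to 80.3, which takes genes as independent). This counts against a single faulty slide as the source of all 78 differences. But the median difference was 1.183 on the other slides against 3.758, and over all genes the differences correlated at 0.033. Exchanged labels in pair 3 cannot be told apart from correct ones. Of 115 genes over 0.7 with one sign in pairs 1 and 2, 48.7% kept it in pair 3. Turning pair 3 gave 181 genes unadjusted against 380 but 2 past the adjusted threshold against 0. Turning pair 1 gave 393 genes unadjusted and 0 past the adjusted threshold. RNA of animals at different points of the moulting cycle is a candidate explanation. The cuticle and ecdysone-response lists both held smaller F-test p-values for pair differences than other genes. In the one-sided camera test the largest p of these lists was 0.00111 (adjusted p of 0.0116, and 0.0106 without the 5 genes). The labels name no stage, and the same test passed for the immune (adjusted p = 0.0248), mitochondrial ribosomal (0.0379) and yolk and chorion lists (0.0415). Of the last list only Yp2 is a yolk or chorion gene. The moulting cycle thus remains a hypothesis found and tested on the same data.

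Of 63 list differences between pairs, 9 passed camera with the preset correlation, and 0 passed with an estimated correlation, where the adjusted p was 0.761 for each. Oxidative phosphorylation genes had a median difference of -0.432 for pair 1 minus pair 2 (adjusted p = 0.00076) and of -0.326 for pair 1 minus pair 3 (adjusted p = 0.00945). Mitochondrial ribosomal protein genes had median differences of -0.59 for pair 1 minus pair 2 (adjusted p = 5.71e-06) and -0.515 for pair 1 minus pair 3 (adjusted p = 0.000214). Ecdysone-response genes had 1.164 for pair 1 minus pair 3 (adjusted p = 0.00147) and 0.209 for pair 2 minus pair 3 (adjusted p = 0.00721). For pair 2 minus pair 3, cytochrome P450 genes had 0.193 (adjusted p = 0.00945) and the gut and peritrophic matrix list 0.173 (adjusted p = 0.0113). Cuticle protein genes had 0.048 for pair 2 minus pair 3 (adjusted p = 0.0306), which turned to -0.082 without centring. The other 8 differences kept their sign without centring, after scaling and after quantile normalisation, but several were smaller without centring. Oxidative phosphorylation then had -0.197 and -0.221 for pair 1 minus pairs 2 and 3, and mitochondrial ribosomal proteins -0.356 for pair 1 minus pair 2. The cytochrome P450, ecdysone-response and gut and peritrophic matrix lists had 0.063, 0.079 and 0.043 for pair 2 minus pair 3. No value lay far from the others in the 8 groups of columns tested.

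By rank, ratios of pairs 2 and 3 went together across genes and pair 1 stood apart (Spearman 0.351 against 0.069 and -0.082), but by Pearson correlation pairs 1 and 2 (0.161) matched pairs 2 and 3 (0.17). A technical batch of slides is a candidate explanation, since the channel component, in which a diet response cancels, also correlated at 0.485 between pairs 2 and 3 against 0.035 and -0.02 with pair 1 (Spearman; Pearson 0.338 against 0.1 and 0.083). A structure of the slides that does not turn with the dyes stays open, since turned slides of opposite orientation in pairs 2 and 3 had a mean correlation of -0.051 and slides of one orientation 0.404. Diet and channel effects of like size also give values near 0 between opposite orientations, so both cannot be told apart. A biological difference between the pairs was not tested.

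The positive shifts of the muscle, cytochrome P450 and heat shock lists were set against a single pair and shared noise. A single pair as the whole source is argued against for muscle, whose lowest median without 1 pair was 0.2933, with a highest adjusted p of 0.033. For cytochrome P450 genes the medians without pairs 1, 2 and 3 were 0.144, 0.1487 and 0.2152 against 0.169, which counts against it, but with adjusted p up to 0.0873 it is not excluded, and for heat shock genes it stays open (0.1043, highest adjusted p = 0.206). Shared noise between the members stays open for all 3 lists, since the smallest p with an estimated correlation was 0.103, from a fit with 2 residual degrees of freedom. The diet, as the design names it, remains among the open explanations.

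Splits of the 6 slides into 3 and 3 number 10, too few for a share under 0.05. In the fit without a replicate block the real split gave 486 genes at an unadjusted p under 0.05, and the highest other split 492. At least 486 genes were given by 2 of the 10 splits, the real one included. At the adjusted threshold the real split gave 1 gene and the highest other 6. Over the 4 sign patterns of the 3 pairs, also too few, the real pattern gave 380 genes and the highest other, with pair 1 turned, 393. At least 380 genes were given by 2 patterns, the real one included.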

How the results depend on the processing

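Centring each spot set, gene means over probes with both slides of a pair, and list shifts after scaling or quantile normalisation, were tested only after the data were seen. For diet, limma gave 0 genes past the adjusted threshold in most settings, 1 with the flip pair as a random replicate block, 1 with no replicate block and 173 with the 18 spot sets as units and the slide as a random block, where 647 passed unadjusted. The last fit counts repeat spots as replicates. Without 1 pair 0 genes passed, and unadjusted counts ranged from 210 to 577. The channel effect gave 2 genes without centring, 2 after quantile normalisation, 2 with the median of spot sets, and 0 to 12 without 1 pair, with unadjusted counts of 212 to 853. Differences between pairs gave 12 genes without centring, 108 over probes with all values, where the prior degrees of freedom were 6.15 against 2.69, and 26 with the median of spot sets. With at least 2 pairs per gene this test was not run, since it needs all 3. Lists past the threshold were 0 with an estimated correlation, 0 with fry in one direction, 0 with fry in either direction, and 2 to 4 without 1 pair. With values taken as already turned, signs reversed for CG10962 (-0.2728), dlg1 (-0.4636), Cyp9b2 (-0.5856), sano (-0.175), CG3270 (-0.2917), CG42322 (-0.3542), Pdk1 (0.04665), CG9021 (0.8391) and CG32302 (0.1347). Genes that kept their sign then also had smaller ratios, such as mag (0.32), CG10912 (-0.09), Kap3 (-0.01), CG6933 (-0.01) and Acox57D-p (0.01). Pooled over all settings, these included, 348 values of named genes kept their sign and did not pass the adjusted threshold, as in the main fit. Another 16 newly passed it, all in fits that count slides of a pair or spot sets as replicates. The 348 values do not measure robustness. Several fits share the main estimate, and genes chosen for one sign in all 3 pairs keep it when 1 pair is left out. Of the list values, 23 kept their side and 13 lost it. No centring moved the SD between spot sets to 0.4277 and the median of all ratios to 0.088, -0.124 and -0.003 in pairs 1 to 3, and 49.4% of genes past the unadjusted threshold were then positive, against 54.7%. The cause was not tested where none is given, and signal over background, which limits dim spots, is unknown.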

Other observations

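The genes in this part were chosen after their values were seen, and no further test was run on them. Below the 5 genes past the threshold, CG3108, ImpE2, CG9747, Gasp and unc-5 were among the named genes that came close in the test for differences between pairs. CG3108 had ratios of 5.23, 0.80 and -3.62 in pairs 1, 2 and 3 (limma F test, adjusted p = 0.052). The ecdysone-inducible gene ImpE2 had 3.76, 4.29 and -4.09 (adjusted p = 0.0554), and the chitin-binding protein gene Gasp had 2.56, 2.60 and -1.49 (adjusted p = 0.0555). CG9747 and unc-5 had adjusted p of 0.0554 and 0.0555, and none of the 5 passed over all genes tested.

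Immune genes had smaller F-test p-values for pair differences than other genes as a list of 4 (one-sided camera test with the preset correlation, adjusted p = 0.0248). In that list PGRP-LD had -0.13, 2.57 and -0.68 in pairs 1, 2 and 3. The camera test gave 0.0379 for 18 mitochondrial ribosomal proteins, 0.0415 for the 4 genes of the yolk and chorion list and 0.958 for 14 proteasome genes (adjusted p). Of the 18 mitochondrial ribosomal proteins only 1 (5.6%) had an unadjusted p under 0.05 in the F test. In the yolk and chorion list only Yp2 is a yolk or chorion gene, and its own adjusted p was 0.817 (limma F test). Over genes with all 18 values the mitochondrial ribosomal list no longer passed (adjusted p = 0.0644), and the immune and yolk lists had too few genes.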
